A study of Mus musculus with 2 samples.

How the data were processed

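Exosomal small RNA was measured in 2 mouse libraries, 1 from mesenchymal stem cells (MSCs) of the C57BL/6 strain and 1 from NIH3T3 cells, a fibroblast line of NIH Swiss origin that served as the control. Per the labels' protocols, both cell types grew in αMEM with 5% fetal bovine serum for 72 hours, RNA was taken from the supernatant with an exoRNeasy kit, and sequencing libraries were built with the QIAseq miRNA kit. The same protocols also speak of a miRNA microarray. The deposited table held whole-number raw counts, so the values were treated as sequencing counts, and the counting intervals rest on that reading. The serum itself can contain vesicles and miRNAs, and whether it was depleted of them was not given in the sources used here.

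The deposited table held 1374 entries, of which 1214 were mature miRNAs and 160 were piRNAs, a class of small RNA mostly known from the germline. Of the miRNA entries, 6 merged several names that share a mature sequence. Per the file headers, one pair of columns held raw counts, and these were whole numbers in the deposited table. Whether they counted reads or molecular identifiers, and which aligner, counter and annotation release were used, was not given in the sources used here. The genome build was mm10, per the submitters' processing notes. Per the file headers, the other pair of columns held normalized values, which were on a log2 scale. Each deposited log2 value equalled the log2 of the raw count times 1 factor per library, 0.655 for the MSC library and 1.84 for the NIH3T3 library, when checked over all entries, with 0 where the raw count was 0 or the product was under 1. How the authors chose the factors was not given in the sources used here. Every entry had 10 or more raw counts in at least 1 library, so miRNAs below that level in both were not analysed here. Because the MSC library was deeper, that minimum lay at a lower relative level there.

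The raw counts summed to 2500459 in the MSC library and 1037147 in the NIH3T3 library, and the miRNA counts to 1028186 and 431007. A miRNA entered the comparison if it reached 100 CPM of the miRNA total in at least 1 library, which was 103 raw counts for MSC exosomes and 43.1 for NIH3T3 exosomes. The log2 ratio was that of MSC over NIH3T3 exosomes on the deposited scale, after adding 1 CPM of the mean miRNA total, 0.734 on that scale. A miRNA was called higher or lower at a difference of 2-fold or more. Each group had 1 library, so no test was made, and calls were made by size alone. The 95% interval of each ratio was the exact conditional interval of the raw counts (Clopper-Pearson), scaled by the library factors and without the added constant. Shares of counts have 95% Wilson intervals. A count of 0 was taken to allow up to 3 counts in that library, and a fold against it is given as a lower bound. This limit is one-sided, while the intervals are two-sided and can begin lower. Intervals and bounds cover counting error only. If the counts are reads, PCR copies among them are not independent molecules, and the intervals are then too narrow even for counting error.

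There were 24 fixed miRNA lists: families and clusters (let-7, miR-17-92 and paralogs, Dlk1-Dio3, Sfmbt2, Hox clusters, miR-23/27/24, miR-29, miR-30, miR-15/16, miR-34, miR-221/222, miR-181, miR-130/148/301, inflammation-linked, H19 and Igf2) and cell type sets (mesenchymal, haematopoietic, endothelial, epithelial, neural, striated muscle, hepatic, pluripotency, serum carry-over). For the 15 lists with at least 3 members over the floor, the median log2 ratio was ranked among the medians of 10000 random lists of the same size, matched on mean level in 5 bins. A list was said to stand apart below percentile 2.5 or above 97.5, as a description of these libraries. The miRNAs named were the 10 most abundant of each library, the 12 with the largest ratio in each direction, up to 4 members of each list with the highest level, and any cell type marker over the floor. Other miRNAs are named where a count or region singled them out, and the text says that they were chosen after their values were seen. Groups, lists, floor, size rule and naming rule were fixed before the data were examined.

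Positions are those of the table, in mm10. All 1206 miRNA entries with a position fell inside a hairpin of the GENCODE M21 annotation of the same build, from which host genes were taken. Mature sequences were taken from the annotated hairpin transcripts at these positions. They were searched for matches of 18 bases in the annotated transcripts of other genes, with introns left out. Members of a family that differ by a few bases, such as miR-196a and miR-196b, let-7 or miR-199, can exchange reads in a way that depends on the counting, so their split is uncertain. The table gave 52 miRNA entries more than 1 position, and each was counted once.

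Alternatives were scaling by the miRNA total, centring on the median ratio, scaling without the 10 most abundant miRNAs of each library, added constants of 10 and 0.1 CPM, floors of 10 and 1000 CPM and none, a 4-fold rule, families summed before the ratio, and CPM of all entries. A further 4 were added after the data had been seen: leaving out miRNAs numbered above 1000, leaving out the Dlk1-Dio3 list, scaling without miR-3473b, and a relative minimum for piRNAs. The steps were tested on simulated data for the MSC against NIH3T3 comparison, in which 200 entries and a planted list of 10 were altered and 282 miRNAs lay over the floor. All altered miRNAs over the floor were recovered (100%), 19 at a true log2 ratio of -3, 10 at -1.5, 14 at 1.5 and 36 at 3, and 0% of 203 unaltered ones were called. The planted list ranked at percentile 0. Of 200 unaltered random lists, 4.5% stood apart. The simulated counts held Poisson counting noise only, without variation between cultures or library preparations. They were scaled by known totals, so no scaling error entered. The unaltered lists were random draws ranked among random draws, so by construction few could stand apart. These rates therefore check the steps and are not error rates for a comparison of single real libraries. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.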

Results

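The data were small RNA counts from exosomes, vesicles that cells release into their medium. The exosomes came from mouse mesenchymal stem cells (MSCs), stromal cells that can form bone, cartilage and fat, and from NIH3T3 cells, an immortalised mouse fibroblast line. The stated question was which miRNAs were enriched in MSC exosomes, with NIH3T3 exosomes as the control. Each group held 1 library, so there were no replicates, no test was made, and none of the differences has a replicate check. The MSC library held 2500459 counts, 1028186 of them on miRNAs, and the NIH3T3 library 1037147, of which 431007 were on miRNAs. The median miRNA entry had 22.5 raw counts in the MSC library and 11 in the NIH3T3 library. A count of 0 allowed a level of up to 2.92 CPM of the miRNA total in the MSC library and 6.96 CPM in the NIH3T3 library. Values in brackets are 95% intervals for counting error.

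The most abundant miRNAs were largely shared. The entry for miR-199a-3p and miR-199b-3p, which are identical and belong to the mesenchymal set, led both libraries, with 16.8% of miRNA counts in MSC exosomes (16.7 to 16.8) and 15.4% in NIH3T3 exosomes (15.3 to 15.5). The differentiation-associated let-7i-5p, let-7b-5p and let-7c-5p, with miR-221-3p and the cell cycle regulator miR-16-5p, were also among the 10 most abundant of both, so that 6 entries were shared. Their log2 ratios lay within the 2-fold bounds, at -0.12 for miR-199a-3p, -0.71 for let-7i-5p, 0.34 for let-7b-5p, -0.53 for let-7c-5p, -0.38 for miR-221-3p and 0.06 for miR-16-5p. The other 4 of the MSC library were miR-125b-5p, the mammalian counterpart of the worm lin-4, miR-143-3p, a smooth muscle and stromal miRNA, miR-29a-3p, which represses collagen mRNAs, and miR-210-3p, which is induced by hypoxia.

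Of these 4, miR-125b-5p had 54096 counts in MSC and 5726 in NIH3T3 exosomes (log2 ratio 1.75, 1.71 to 1.79), and miR-143-3p had 38634 and 3690 (1.90, 1.85 to 1.95). For miR-210-3p the log2 ratio was 1.13 (1.08 to 1.18), and miR-29a-3p differed by less than 2-fold (0.56). In the NIH3T3 library the other 4 were miR-3473b, miR-146b-5p, let-7f-5p and miR-31-5p. miR-3473b took 14.9% of NIH3T3 miRNA counts (14.8 to 15.0) and 0.737% of those of MSC exosomes (0.721 to 0.754). Its mature sequence, at chromosome 10, 41670774 to 41670793, shared 18 bases with transcripts of 511 other annotated genes. The 10 most abundant miRNAs held 53.4% of MSC miRNA counts (53.3 to 53.5) and 63.2% of NIH3T3 miRNA counts (63.1 to 63.4).

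**Figure D1:**
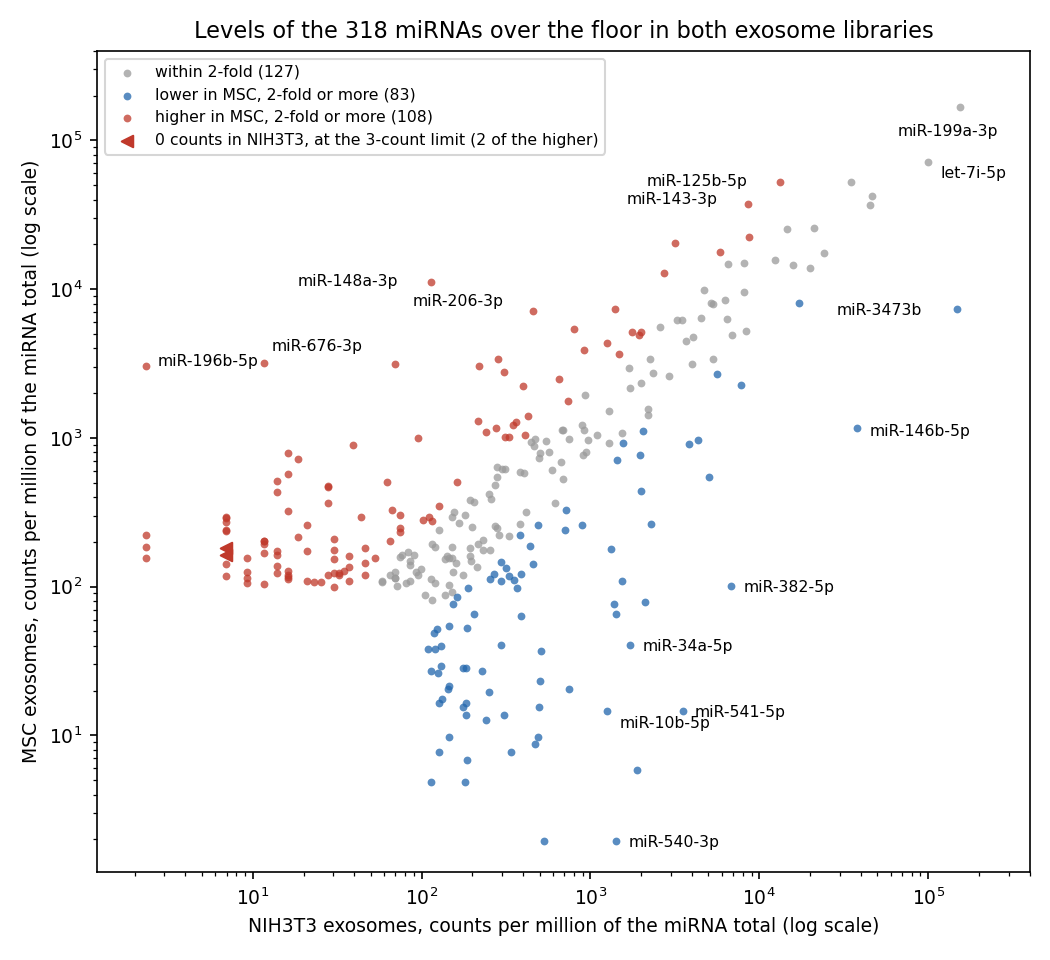
Level of each of the 318 miRNAs over the floor in NIH3T3 exosomes (horizontal) and MSC exosomes (vertical), both in CPM of the miRNA total on log axes, coloured by the 2-fold call made on the deposited scale. There are 108 higher, 83 lower and 127 within 2-fold, and triangles mark the 2 miRNAs with 0 counts in the NIH3T3 library, drawn at the level that 3 counts would give.

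Compared directly, MSC exosomes carried more of the Hox-cluster miRNA miR-196b-5p, of miR-676-3p and of miR-148a-3p, a repressor of the DNA methyltransferase Dnmt1, and less of many miRNAs of the imprinted Dlk1-Dio3 cluster. miR-196b-5p had 3124 counts in MSC and 1 in NIH3T3 exosomes (log2 ratio 9.64, 7.64 to 15.42), and miR-676-3p had 3269 and 5 (7.75, 6.64 to 9.49). For miR-148a-3p the counts were 11481 and 49, an 82.8-fold difference (6.37, 5.98 to 6.82). In the other direction miR-540-3p had 2 counts in MSC and 614 in NIH3T3 exosomes (-9.11, -12.80 to -7.89), and the NF-κB-induced miR-146b-5p had 1198 and 16409 (-5.26, -5.35 to -5.18). In all, 108 of 318 miRNAs were 2-fold or more higher in MSC exosomes, 83 were lower and 127 were within these bounds.

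Of the miRNAs called higher, 87 had a counting interval wholly beyond 2-fold, as had 72 of those called lower. Entries numbered above 1000, which were annotated later, made up 39 of the 108 higher miRNAs and 15 of the 83 lower ones. The libraries correlated across miRNAs with a Spearman rho of 0.51, where miRNAs are not independent replicates. The median log2 ratio of all 318 was 0.28. It moved to 0.51 when each library was scaled by its own miRNA total and to 0.11 without the 10 most abundant miRNAs of each, while centring lowered all ratios by 0.28 and gave 97 higher and 99 lower. Ratios close to a bound therefore depended on the scaling, and the list members and named miRNAs concerned were picked out for this after their values were seen. When centred, miR-210-3p (0.86), miR-27a-3p (0.84) and miR-30a-5p (0.80) were no longer higher, while miR-31-5p (-1.05), let-7d-5p (-1.13), miR-98-5p (-1.05), miR-30e-5p (-1.02) and miR-30e-3p (-1.13) were lower. Scaled by the miRNA total, miR-20a-5p (-0.80) was no longer lower, while miR-199a-5p (1.16), miR-222-3p (1.06), miR-25-3p (1.05), miR-301a-3p (1.19) and miR-30a-3p (1.07) were higher.

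The 12 miRNAs with the largest ratios in favour of MSC exosomes differed in level. Beside the 3 above, miR-196a-5p, which cleaves Hoxb8 mRNA, had 3232 counts against 30 (5.24, 4.75 to 5.83), miR-3070-5p 819 against 7 (5.30, 4.33 to 6.70) and miR-201-3p 741 against 8 (4.98, 4.06 to 6.26). The others had fewer counts in MSC exosomes. miR-691 and miR-500-5p had 188 and 168 counts in MSC exosomes and 0 in NIH3T3 exosomes, so that against a limit of 3 counts they were at least 22.3-fold and 19.9-fold higher. miR-759 had 228 counts against 1 (5.87, 3.85 to 11.65) and miR-3090-3p 191 against 1 (5.61, 3.59 to 11.40). miR-292b-5p had 160 against 1 (5.36, 3.33 to 11.14). It lies among the miRNAs of an embryonic stem cell cluster, but on the strand opposite to miR-290a and miR-294. miR-5135, with 3 counts in NIH3T3 exosomes, had a log2 ratio of 4.98 (3.60 to 7.44). The opposite arm of the miR-500 hairpin, miR-500-3p, was picked out after its value was seen and was lower in MSC exosomes (247 against 307 counts, -1.80).

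Among the 12 with the largest ratios in favour of NIH3T3 exosomes, 6 were Dlk1-Dio3 miRNAs. The other 6 were miR-10b-5p and miR-10b-3p of the Hoxd cluster, miR-181d-5p, the p53 target miR-34a-5p, miR-9-5p, a miRNA of neural progenitors, and miR-146b-5p. miR-10b-5p had 15 counts in MSC and 542 in NIH3T3 exosomes (-6.56, -7.51 to -5.93), miR-34a-5p 42 and 743 (-5.60, -6.12 to -5.19), and miR-9-5p 21 and 322 (-5.36, -6.14 to -4.79).

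In mm10, miR-196b-5p lay on chromosome 6 at 52230129 to 52230150, inside an exon of a Hoxa9 transcript, and miR-148a-3p on the same chromosome at 51269829 to 51269850, between genes. miR-676-3p lay on chromosome X at 100381151 to 100381171, in an intron of Eda. miR-10b-5p was on chromosome 2 at 74726074 to 74726096, in an intron of Hoxd4, and miR-146b-5p on chromosome 19 at 46342790 to 46342811, in an intron of Mfsd13a. miR-34a-5p lay between genes on chromosome 4, at 150068473 to 150068494.

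Dlk1-Dio3 miRNAs, which are expressed from the maternal copy of chromosome 12, were lower in MSC exosomes without exception among the 19 list members over the floor. Their median log2 ratio was -4.63, at percentile 0 of the random lists, and 18 of the 19 had an interval wholly below -1. The members come from a single region, and both arms of miR-434 are among them. They are thus not independent, which the random lists do not reflect. Of these 19, however, 17 passed the floor through their NIH3T3 level alone, and without a floor 25 of the 48 list entries had an interval wholly below -1. miR-127-3p, encoded antisense to Rtl1, had 562 counts in MSC and 2169 in NIH3T3 exosomes (-3.44, -3.57 to -3.30). For miR-382-5p, in an intron of Mirg, the counts were 104 and 2930 (-6.29, -6.60 to -6.02). miR-541-5p had 15 and 1514 (-8.04, -8.99 to -7.42) and miR-434-5p 6 and 817 (-8.33, -10.03 to -7.45). The smallest difference was that of miR-494-3p, with 50 and 51 counts, which was 2.82-fold lower in MSC exosomes (log2 interval -2.11 to -0.93) and was picked out after its value was seen.

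By position the region spanned chromosome 12 from 109563744 to 109743784 and held 24 miRNAs over the floor, of which 21 were lower in MSC exosomes. The exceptions were miR-3070-5p, which was higher and has 2 positions in the table, and miR-432 and miR-329-5p, within 2-fold at -0.40 and 0.06, the last 2 picked out after their values were seen. The span was that of the list members, and miR-3072-5p, also picked out afterwards, lay just beyond it at 109747893 to 109747914, in an intron of Mirg, and was higher in MSC exosomes (110 against 11 counts, 1.80, 0.94 to 2.88). With a floor of 10 CPM, 36 of 48 list members were lower, 1 was higher and 11 were neither, with a median of -2.38.

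**Figure D2:**
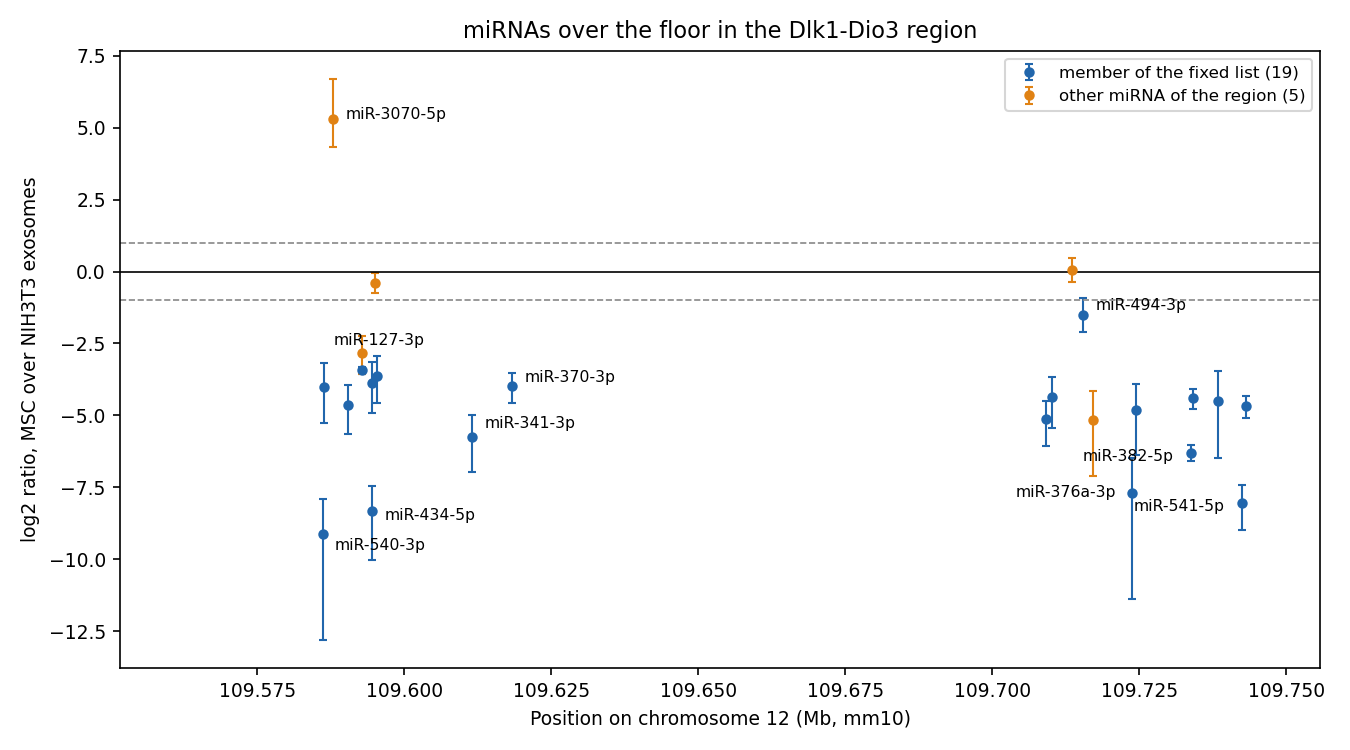
The log2 ratio of MSC over NIH3T3 exosomes for the 24 miRNAs over the floor in the Dlk1-Dio3 region, by position on chromosome 12 in Mb (mm10), with 95% counting intervals of the raw count ratio as bars and dashed lines at the 2-fold bounds. All 19 members of the fixed list lie below the lower bound, down to -9.11, and 1 of the other 5 miRNAs lies above the upper bound, at 5.30.

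The seed-related miR-130, miR-148 and miR-301 families were the only list that stood apart on the higher side, with a median log2 ratio of 1.92 at percentile 99.7. Of 6 members over the floor, 4 were higher in MSC exosomes and 2 were within 2-fold. Under the floor, miR-301b-3p, picked out after its value was seen, was lower (27 against 29 counts, -1.55, -2.40 to -0.79). With a floor of 10 CPM, 4 were higher, 1 was lower and 2 were neither, at percentile 99.4. Besides miR-148a-3p, miR-152-3p had 13272 counts against 1183, a 3.99-fold difference (log2 interval 1.91 to 2.09), while the log2 ratios were 2.25 (2.03 to 2.49) for miR-148b-3p and 1.84 (1.69 to 1.99) for miR-130a-3p. The Hox-cluster miRNAs, whose expression follows position along the body axis, split into opposite groups: miR-196a-5p and miR-196b-5p were higher in MSC exosomes, while miR-10b-5p, miR-10b-3p and miR-10a-5p (-3.05, picked out after its value was seen) were lower. miR-615-3p of the Hoxc cluster was at -0.20. The list median was -1.63 at percentile 4.29, and it was 5.24 at a floor of 1000 CPM. Over the alternatives its percentile ran from 1.75, at a floor of 10 CPM, to 97.2, at 1000 CPM.

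Members of the inflammation-linked list also went both ways, with 4 lower in MSC exosomes, 2 higher and 1 within 2-fold. The lower ones included miR-9-5p and miR-146b-5p, given above. miR-146a-5p, which represses Traf6 and Irak1, had 271 counts in MSC and 983 in NIH3T3 exosomes (-3.34, -3.55 to -3.15), and miR-155-5p, induced in activated immune cells and picked out after its value was seen, had 113 and 662 (-4.03, -4.34 to -3.75). miR-125b-5p was higher, as above, and miR-125a-5p was at 0.66. The list median of -3.34 stood apart at percentile 0.075, but a floor of 10 CPM, which added 2 higher members, turned it to 0.66 at percentile 90.7. The 5 miRNAs of the p53-responsive miR-34 family were all lower in MSC exosomes, with a median of -2.30 at percentile 2.16. Some passed the floor through their NIH3T3 level alone, such as miR-34a-5p (40.8 CPM in MSC exosomes). The 4 entries from miR-34b and miR-34c lie in a single cluster, so the members are not independent, which the random lists do not reflect. The most abundant, miR-34c-5p, had 938 and 1652 counts (-2.30, -2.42 to -2.19), and miR-34b-5p was at -1.89. The miR-34 list no longer stood apart, at percentile 3.75, when floor and ratio were taken on CPM of all entries.

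The remaining families did not stand apart at the main floor. All 4 miR-181 miRNAs were lower in MSC exosomes, miR-181d-5p the most (9 against 203 counts, -5.82, -7.13 to -5.03) and miR-181a-5p the least (-1.90). The list median was -3.01 at percentile 3.61 (0.79 at a floor of 10 CPM and 13.9 on CPM of all entries). miR-181d-5p and miR-181c-5p passed the floor through their NIH3T3 level alone (8.75 and 7.78 CPM in MSC exosomes). Of 9 let-7 miRNAs, 7 were within 2-fold and 2 were lower, let-7a-5p (-1.33) and let-7e-5p (-1.30), both picked out after their values were seen, and the median was -0.72 at percentile 4.37 (2.01 at a floor of 1000 CPM and 8.72 at 10 CPM). The Myc-driven miR-17-92 cluster and its paralogs had 2 higher members, 2 lower and 3 neither, with a median of 0.60 at percentile 78.3. miR-19b-3p, which has 2 positions in the table, was higher (1.70), and miR-20a-5p was lower (-1.03). Of 5 miR-23/27/24 members, miR-27b-3p (1.29) and miR-27a-3p (1.11) were higher and 3 were neither (median 0.58, percentile 75.6). The 3 collagen-repressing miR-29 miRNAs were within 2-fold (median 0.42, percentile 64.3), as were 6 of 7 miR-30 miRNAs, while miR-30a-5p was at 1.08 (median 0.28, percentile 54.8).

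In the miR-15/16 family 2 of 5 were higher, miR-322-5p (1.56) and miR-15a-5p (2.83-fold), 1 was lower and 2 were neither (median 0.07, percentile 46.6). miR-221-3p and miR-222-3p, repressors of the cell cycle inhibitor Cdkn1b, were within 2-fold (-0.38 and 0.83). Of the 15 entries of the Sfmbt2 list, 2 of which the table places on chromosome 13 rather than at Sfmbt2 on chromosome 2, 1 was over the floor, miR-669c-5p, which was lower in MSC exosomes (65 against 168 counts, -2.84, -3.30 to -2.44). At a floor of 10 CPM, where most of the entries had few counts, 11 of 14 were lower, 3 were neither and 0 were higher, with a median of -1.95 at percentile 0. At the imprinted growth loci, miR-483-5p of Igf2 was the 1 entry over the floor and was lower (20 against 108 counts, -3.85, -4.69 to -3.23). miR-675-5p of H19, just under the floor, went the other way, with 97 counts against 9 (1.89, 0.96 to 3.11).

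**Figure D3:**
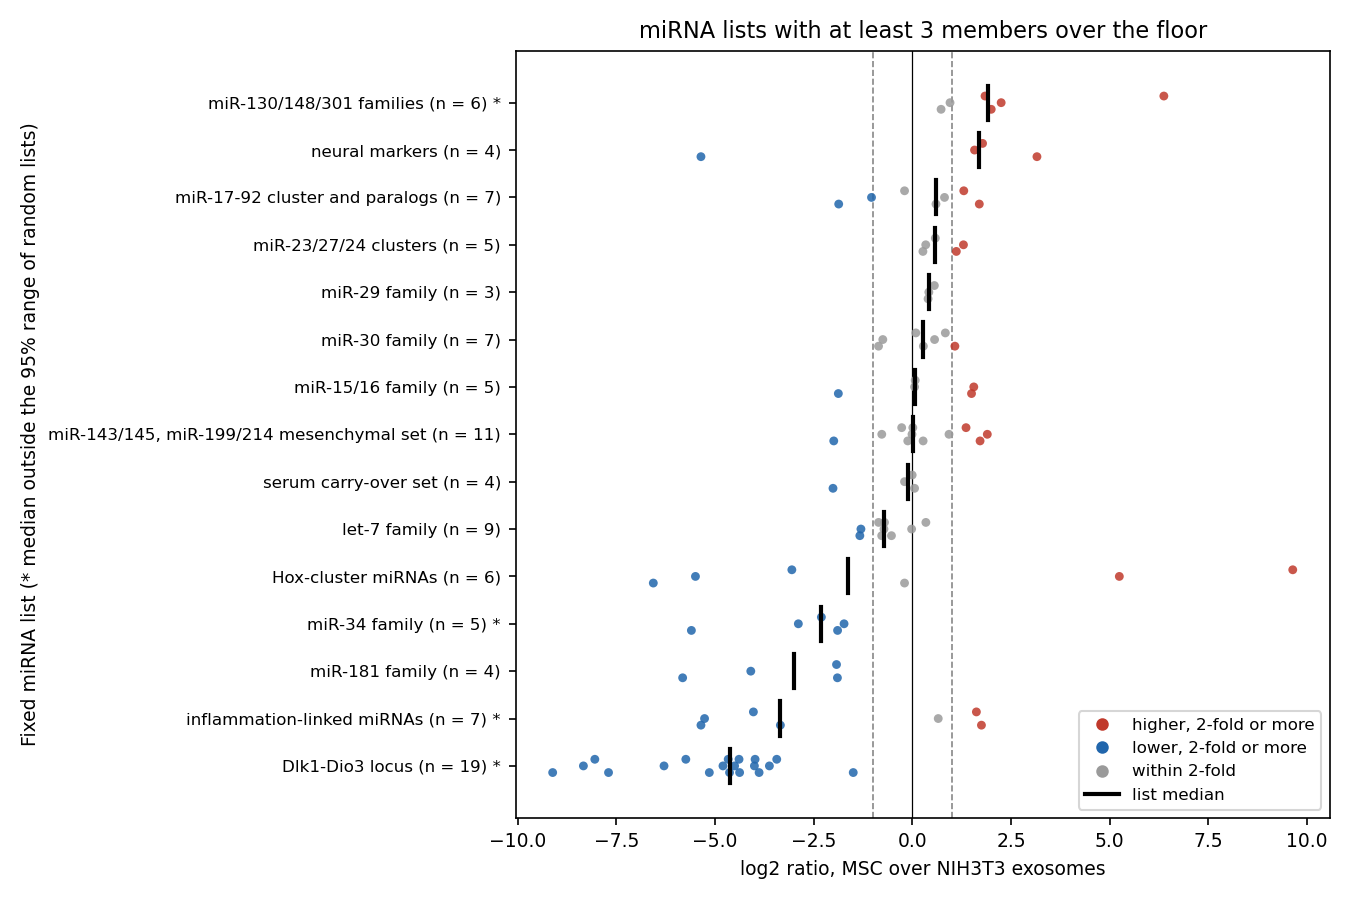
Log2 ratios of MSC over NIH3T3 exosomes for the members over the floor (points, coloured by the 2-fold call) of the 15 lists with at least 3 of them, with list medians as black bars and dashed lines at the 2-fold bounds. Stars mark the 4 lists whose median lay outside the central 95% of 10000 random lists: Dlk1-Dio3 (-4.63), inflammation-linked (-3.34) and miR-34 (-2.30) on the lower side and the miR-130, miR-148 and miR-301 families (1.92) on the higher side.

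Of the mesenchymal miRNAs most were within 2-fold between the libraries, and the miR-143 and miR-145 cluster and miR-199b-5p were not. Of 11 members, miR-143-3p, miR-145a-5p (18192 against 2524 counts, 1.36, 1.30 to 1.42) and miR-145a-3p (1.72) were higher in MSC exosomes, miR-199b-5p was lower (-1.99), and 7 were within 2-fold, among them miR-21a-5p (-0.27), miR-22-3p (0.01) and miR-214-3p (0.27). The median was 0.01 at percentile 34.0.

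Among the markers of single other cell types, those with the most counts in MSC exosomes were miR-122-5p and miR-206-3p. The skeletal muscle miRNA miR-206-3p had 7383 counts in MSC and 198 in NIH3T3 exosomes (3.73, 3.53 to 3.94), whereas its fellow muscle markers miR-133a-3p (72 and 18 counts) and miR-208b-3p (40 and 4) were under the floor. The hepatocyte miRNA miR-122-5p had 9759 and 3486 counts, with a log2 ratio of -0.00 on the deposited scale (-0.06 to 0.05), 0.23 scaled by the miRNA total and -0.28 centred. In the serum carry-over set, which contains miR-122-5p and miR-16-5p, 3 of 4 members were within 2-fold and miR-423-5p was lower in MSC exosomes (-2.01, -2.09 to -1.93), with a median of -0.10 at percentile 42.8. The blood cell miRNAs over the floor, miR-342-3p (185 and 569 counts, -3.10) and miR-142a-3p (121 and 142 counts, -1.71), and the endothelial miR-126a-3p (337 and 309 counts, -1.36), were lower in MSC exosomes. At a floor of 10 CPM, however, 6 of the 9 blood cell entries were within 2-fold and 3 were lower, with a median of -0.16 at percentile 45.1. Of the neural set miR-128-3p (1.58), miR-129-5p (1.78) and miR-219a-5p (3.16) were higher and miR-9-5p lower, with a median of 1.68 at percentile 92.8. No epithelial marker and no fixed pluripotency marker was over the floor, where the most abundant had 28 counts (miR-205-5p) and 37 counts (miR-290a-5p) in the MSC library.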

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

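The piRNA values were looked at only after the table had been seen, and no test was made on them. More counts fell on piRNA entries than on miRNAs in both libraries, 58.9% of all counts in the MSC library (58.8 to 58.9) and 58.4% in the NIH3T3 library (58.3 to 58.5). These entries drew attention because the comparison of miRNAs did not use them. A single piRNA, piR_000620, which the table listed at 2 positions, held 54.1% of all counts in the MSC library and 55.0% in the NIH3T3 library. The counts were not split alike between its positions, with a ratio of 1.87 between the chromosome 3 and chromosome 18 entries in the MSC library and 1.21 in the NIH3T3 library. Of 64 piRNA entries with 100 or more raw counts, 19 were 2-fold or more higher in MSC exosomes and 4 were lower. That minimum lies at a lower relative level in the deeper MSC library. With a minimum of 100 CPM of all counts of a library in its place, chosen after seeing the data, 12 of 39 were higher and 4 were lower. The genome build of the piRNA positions was not given apart from that of the table, and the origin of these counts was not tested.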

How the results depend on the processing

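Leaving out miRNAs numbered above 1000, the Dlk1-Dio3 list or miR-3473b were alternatives chosen after seeing the data, as was the relative minimum for piRNAs, and the others were planned. Under the scalings and added constants, 458 log2 ratios of named miRNAs moved by less than their counting interval and 184 by more. The sign changed in 21 of all these values, from 12 miRNAs whose main log2 ratio was at most 0.27 in size, and in 0 of those 2-fold or more apart. The Dlk1-Dio3 list stood apart under every alternative that gave it a percentile. Scaling moved all ratios nearly alike and so could hardly change the rank of a list. The floor of 10 CPM (percentile 0) and CPM of all entries (0.005) could. At 1000 CPM (0.18) the list members passed the floor through their NIH3T3 level alone, the highest MSC level being 547 CPM. Their ratios there could only favour NIH3T3 exosomes. The counts of higher and lower miRNAs stayed within 1.5 times under the scalings to the miRNA total (120 and 76), centred (97 and 99) and without the 10 most abundant miRNAs (100 and 91), and with added constants of 10 CPM (106 and 82) and 0.1 CPM (108 and 83).

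The floor set the counts by construction, since it decides which miRNAs enter. At 10 CPM there were 282 higher and 309 lower with a median log2 ratio of -0.0699, with no floor 289 and 309 with a median of -0.0414, and at 1000 CPM 34 and 25. The 4-fold rule gave 63 and 52. On CPM of all entries, where piRNAs enlarge the total and fewer miRNAs reach the floor, there were 68 and 50, and the top 10 held 22.0% and 26.3% of all counts. Without late-numbered miRNAs 69 were higher and 68 lower. With these entries kept, the excess of higher ones was also absent when centred (97 and 99) and at a floor of 10 CPM. Centring balances the higher and lower counts nearly by construction, and the floor changes which miRNAs enter. These settings therefore do not show what the excess rested on. Leaving out the Dlk1-Dio3 list gave 108 higher and 64 lower. Summing families put the top 10 at 62.8% and 72.4%. At 10 CPM 6 lists stood apart. These were Dlk1-Dio3, miR-34 and the miR-130, miR-148 and miR-301 families as before, the Hox-cluster list (percentile 1.75), the miR-181 list (0.79) and the Sfmbt2 list (0), which had too few members at the main floor. The inflammation-linked list turned to a median of 0.66 at percentile 90.7 there. At 1000 CPM let-7 stood apart (2.01) and the Hox median turned to 5.24, while miR-34 and miR-181 had too few members. The miR-34 list was at 3.75 on CPM of all entries, and the cause was not tested. In the shallower NIH3T3 library 18 miRNAs had 0 counts, against 0 miRNAs in the MSC library, and for these only a bound on the fold can be given.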

Other observations

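The miRNAs in this and the next paragraph, with miR-3473e, miR-574-5p, miR-709 and miR-7667-5p, were chosen after their values were seen, as were the tests on Dlk1-Dio3, on miR-3473b and on fragments of other transcripts. Both arms of miR-140, a miRNA of cartilage encoded within Wwp2 on chromosome 8, were higher in MSC exosomes. miR-140-3p had 21110 counts against 1360 (log2 ratio 2.47, 2.39 to 2.55) and miR-140-5p 2853 against 132 (2.94, 2.69 to 3.21). Near the imprinted Gnas locus on chromosome 2, between 174267058 and 174267575, miR-296-3p (2.51, 2.36 to 2.68), miR-296-5p (3.32, 2.25 to 4.87) and miR-298-5p (3.34, 3.09 to 3.62) were higher. miR-335-3p, in an intron of the imprinted gene Mest, had 491 counts against 12 (3.82, 3.05 to 4.83). All 4 entries of the miR-143 and miR-145 cluster on chromosome 18 were higher, at 1.36 to 2.36. The 3 entries from the miR-181c and miR-181d cluster on chromosome 8 were lower, at -5.82 to -3.65, as were the 4 from miR-34b and miR-34c on chromosome 9, at -2.89 to -1.73.

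The arms of a hairpin come from 1 precursor, and 52 hairpins had both over the floor, 5 of them with an arm that has more than 1 position. In 36 of them the arms lay on the same side of 0, with a Spearman rho of 0.58 across hairpins, which are not independent replicates, and a median difference of 0.79 in log2. The arms of 6 hairpins differed by more than 2. After miR-500 the largest gaps were those of miR-24-1, whose 5p arm was at 4.88 (280 against 3 counts, 3.49 to 7.34) and miR-24-3p at 0.27, and of miR-434, at -8.33 for the 5p arm and -3.88 for the 3p arm. miR-24-3p also has a second locus.

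Dlk1-Dio3 miRNAs were lower as a group in MSC exosomes. The highest median of the list under any scaling was -4.29. The scalings moved all ratios nearly alike, with the largest shift -0.28 when centred. They could not have removed the list's difference from the other miRNAs, so this was no test of scaling. Dilution by serum RNA would have lowered the other miRNAs made by the cells too, and the other miRNAs over the floor had a median of 0.42. How many of these came from the serum was not known, so this could not decide on dilution. The summed counts of all 48 entries, with no floor, gave a log2 ratio of -4.41 with an upper counting limit of -4.33. Counting error as the whole cause would not allow this. However, 10771 of the 11177 NIH3T3 counts came from entries over the floor, most of which passed it through their NIH3T3 level alone. The sums gave -4.87 for these and -1.34 (-1.54 to -1.15, 449 MSC against 406 NIH3T3 counts) for the 29 entries under the floor. The intervals of 22 of those 29 reached -1, so they stay open one by one. A difference between the cell types or their strains may underlie the pattern, but each was represented by 1 library, so this was not tested and cannot be separated from a difference between the cultures.

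miR-3473b held a large share of NIH3T3 miRNA counts. Its sequence matched 18 bases in 511 other annotated genes, against a median of 0 over the miRNAs searched, and the related miR-3473e, with matches in 404 genes, was lower in MSC exosomes too (-2.40). Reads from transcribed repeats are therefore a candidate source. Matching alone does not set the direction, since the unrelated miR-574-5p (61 genes) was at 1.55, miR-709 (78 genes) at 0.81 and miR-7667-5p (53 genes) at -2.44. A difference in miR-3473b itself between the cell types was not tested.

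Entries numbered above 1000 made up 36.1% of the miRNAs higher in MSC exosomes (27.7 to 45.5), 18.1% of the lower (11.3 to 27.7) and 15.0% of the others (9.79 to 22.2). Fragments of other annotated transcripts stay open, since 7.89% of the late-numbered higher entries matched another gene, with an upper limit of 20.8, against 10.2% of the other entries. At a floor of 1000 CPM the share was 8.82% (3.05 to 23.0) among the higher miRNAs and 4.23% among the rest, too few entries to say whether low levels may account for the excess. The other arm was higher for 25% of 16 late-numbered higher entries and for 22.7% of all other arms in the table, which also leaves open whether they are hairpin products made by the MSCs.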
